A study of Mus musculus with 2 samples.

How the data were processed

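PolyA-selected RNA of mouse placenta was profiled by stranded paired-end sequencing in 2 libraries. Per the labels, the tissue was taken from staged pregnant C57BL/6J females of 8 weeks, C57BL/6J being a common inbred mouse strain, and the RNA was depleted of ribosomal RNA, selected for polyA tails and for molecules above a minimum length. Synthetic spike-in RNAs of the ERCC set were added. The labels call the libraries biological replicates 1 and 2, with a separate biosample for each and 1 donor entry for both. The labels say that sex was not collected, and the day of gestation and the number of placentas per sample were not given in the sources used here. All values with ± are the mean and the standard deviation of these 2 replicates (n = 2).

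For each library the authors deposited a table per gene and a table per transcript on build mm10 with GENCODE annotation M4, per the deposited readme files. Per the file headers, the columns are those of RSEM, which shares reads that fit several genes among them. The aligner and the version of RSEM were not given in the sources used here. The expected counts in these deposited tables are estimated read pairs per gene, are not normalised and need not be whole. The TPM values deposited by the authors are transcript levels scaled to a fixed sum, which includes the spike-ins, the phiX control and tRNA-type entries. FPKM values, per the file headers, are scaled by transcript length and by the number of fragments. The percent that each transcript holds of its gene was deposited by the authors in the transcript tables. Per the file headers, the tables also hold a posterior standard deviation of each count, used here as the uncertainty that shared reads leave.

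Older files of the whole series, on build mm9, pool both replicates. Per the deposited readme files, one set of transcript values uses Ensembl release V65, and per the file's own source column another holds models assembled with Cufflinks. The score of a transcript in both deposited sets is proportional to the sum of the RPKM values of both replicates, with the highest set to 1000 in each file. In the deposited junction file the count is the number of reads over the junction and the fraction is an irreproducibility rate. In the deposited contig file the score is an expression level of unstated unit and the fraction is again an irreproducibility rate. The program behind the junctions and contigs was not given in the sources used here. These files also hold 14 fields with values per replicate inside their text, which no label ties to replicate 1 or 2, and those fields were not used. The older gene tables were left out because their score follows only one of these fields. The exons of the assembled models were left out as not needed, and Ensembl V65 exons were used for coordinates only.

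Gene symbols were matched by Ensembl identifier, which gave a symbol for 42462 of 43346 gene entries, and the entries without one held 0.097% of the summed TPM. Coordinates and gene classes on mm10 come from GENCODE release M21, which uses the same build. Another 26248 tRNA-type entries and 96 spike-in entries were kept out of gene counts. A gene counted as detected at a TPM of at least 1 in both replicates. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, which gave TMM scaling and the biological coefficient of variation from a model with an intercept alone. DESeq2 1.42.0 gave alternative size factors. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.

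The series holds 1 group, so no test between conditions was possible and no p-value is given. Levels were described as TPM, and the level of a gene list as the percentile of its median TPM among 10000 random lists of the same size, drawn from the genes with a TPM above 0 in at least 1 replicate. A list was called above the random lists where this percentile reached 97.5 in both replicates. The replicates were compared as 1 library against 1, by the log2 ratio of TMM-scaled CPM with 1 added, among the 15107 genes with a mean expected count of at least 100. Genes were counted at 2-fold or more. A list with at least 5 such members was set against 10000 random lists matched on mean count in 20 bins, and called outside where its median lay at or beyond the 2.5 or 97.5 percentile. These percentiles describe the 2 libraries and not a condition. Intervals of folds and shares are 95% exact binomial (Clopper-Pearson) intervals. They and the limit of 3 counts for a count of 0 cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

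The 26 gene lists, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 25 genes with the highest mean TPM outside the mitochondrial genome, up to 4 detected members with the highest TPM of each list together with the members not detected where these were 3 or fewer, the 10 genes highest in each replicate by log2 ratio, 12 genes for isoform shares, the globins and the sex-linked list. Genes named outside it are said to have been chosen after their values were seen. The alternatives were other TPM minimums, FPKM and posterior mean TPM, other pseudocounts (0.1), denominators without mitochondrial genes and spike-ins, shares of expected counts, other scalings (DESeq2, total counts, spike-ins), a count minimum of 10, folds of 1.5 and 4, the older build, stricter junction thresholds and each replicate alone. A list each of adipocyte and further smooth muscle genes, the removal of genes of uncertain count (a posterior standard deviation above 10% of the count) and the removal of mt-Atp8 were added after seeing the data.

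The total expected count was 163271198 in replicate 1 and 158064756 in replicate 2, of which 156950500 and 152888536 fell on genes. A transcript of 1 kb at these depths would reach an FPKM of about 0.018 to 0.019 with 3 counts. All thresholds used here lie well above this counting limit. A chi-square of the counts of both libraries over genes was 176 times its degrees of freedom, so they differed beyond counting noise. This chi-square takes reads as independent, which amplified reads are not, and only rules out identical counts. The libraries were treated as separate samples because the labels name a separate biosample for each. The scripts were tested on simulated data made from the real means and library sizes of 43346 genes, with 200 genes changed between replicates. With counting noise alone, 8 of 49 genes changed 2-fold, 43 of 46 changed 4-fold, 46 of 47 changed 8-fold and 48 of 48 changed 16-fold passed the 2-fold rule, and 0 of 14921 unchanged genes did. With a simulated coefficient of variation of 30% for every gene, the value recovered was 31.9% (13.4% with counting noise alone, where 0 was simulated), and 21 of 49, 41 of 46, 45 of 48 and 49 of 49 changed genes of these sizes passed, along with 1111 of 14871 unchanged genes. Of 100 unchanged lists drawn from the data with counting noise alone, 5 lay outside the band. The band itself sets about that share for lists of independent genes, so this does not cover lists of genes that vary together.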

Results

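The series is a reference profile of polyA RNA in mouse placenta, the organ of exchange between mother and fetus, with 2 biological replicates of 1 tissue and no second condition. It addresses which genes the sampled tissue expresses and at what level. The total expected count was 163271198 read pairs in replicate 1 and 158064756 in replicate 2. Each value below is the authors' TPM on build mm10 unless another unit is named, with the SD of both replicates after ± (n = 2).

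The most abundant gene outside the mitochondrial genome was Afp, alpha-fetoprotein of the yolk sac and fetal liver (chromosome 5, 90490737 to 90508907, plus strand), at 24867 ± 1383 TPM. It was followed by Hbb-y, an embryonic beta-like globin (chromosome 7, 103851749 to 103853216), at 19745 ± 757. Among trophoblast products, the placental lactogen Prl3b1 (chromosome 13, 27241847 to 27249683) reached 9152 ± 1340, Prl2c3, a proliferin, 7012 ± 2918, and Tpbpa, a marker of the spongiotrophoblast, 6205 ± 1137. The imprinted noncoding RNA H19 (chromosome 7, 142575529 to 142578143) stood at 8225 ± 447. Other genes among the 25 highest were the carriers Apoa1 at 6273 ± 1884, Trf at 5583 ± 595, Ttr at 3476 ± 881 and Apoa2 at 3332 ± 266, the globins Hba-a2, Hba-a1, Hba-x and Hbb-bh1, and Eef1a1, Gapdh, Actb, Rplp1, Rps12 and Rps15a. The 10 most abundant genes held 18.1% ± 1.20 of all TPM and the 25 most abundant held 26.3% ± 1.02, mitochondrial genes included.

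Noncoding entries were also among the 25 highest. Gm42418, annotated as a noncoding gene on chromosome 17 (39846958 to 39848788), was listed at 14098 TPM in replicate 1 and 22666 in replicate 2. Whether its reads stem from a polyA transcript of that gene was not tested. The pseudogenes Gm29216, Gm28437, Gm10925 and Gm10222 lie together on chromosome 1 between 24612407 and 24616197. For Gm28437 the posterior standard deviation was 26.0% of the count in both replicates, and for Gm10925 it was 18.0% and 18.4%. For Gm29216 it was 0.192% and 0.156%, and for Gm10222 1.58% and 1.75%. In counts, these deviations matched those of mt-Co3 for Gm28437, mt-Atp6 for Gm10925, mt-Nd4l for Gm10222 and, nearly, mt-Co1 for Gm29216. Reads shared with these mitochondrial genes leave the levels of Gm28437 and Gm10925 uncertain. The mitochondrial share given below leaves these pseudogenes out. In the mitochondrial genome, mt-Atp8 was listed at 57830 ± 21036 TPM although it held 0.0779% and 0.0723% of the counts. Its effective length in the tables was only 13.2 and 22.0 bases, which inflates TPM.

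**Figure D1:**
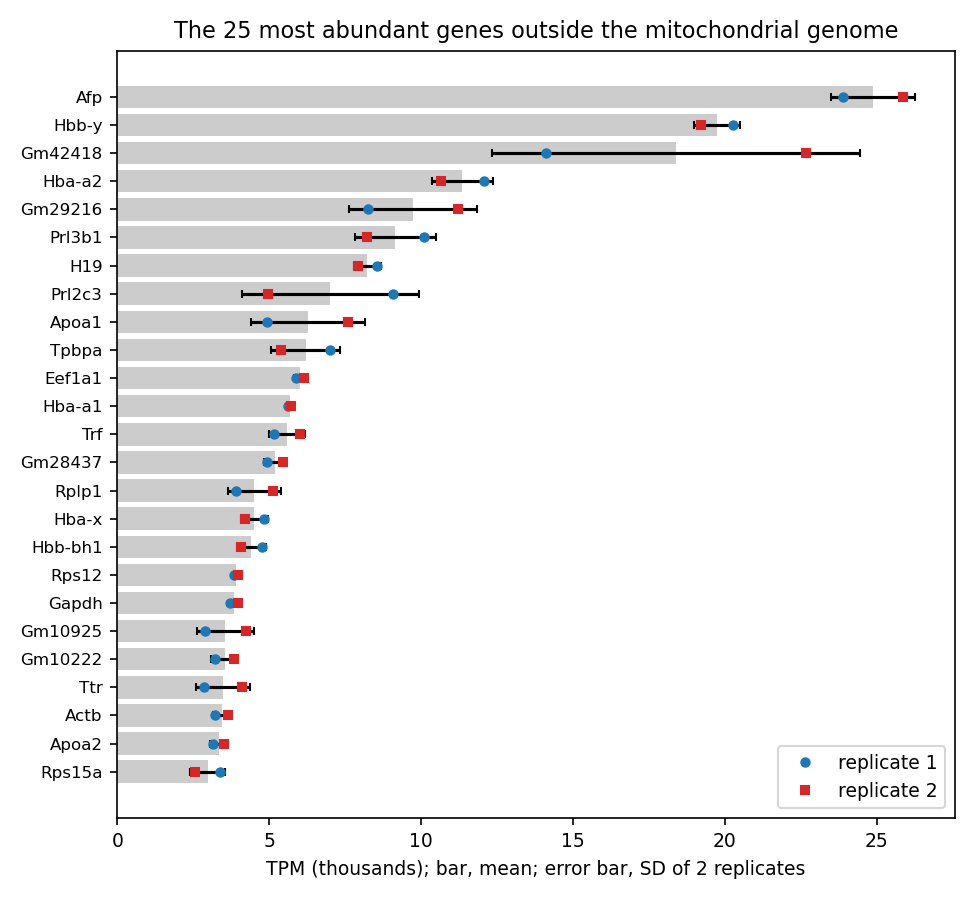
TPM (linear axis, in units of 1000) of the 25 most abundant genes outside the mitochondrial genome; bars are means, error bars the SD of 2 replicates, circles replicate 1 and squares replicate 2. Afp leads at 24867 ± 1383 TPM, and Gm42418 and Prl2c3 show the widest gaps between the replicates.

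In both replicates 13371 genes were detected, 12450 of them protein coding, and these coding genes held 86.4% ± 0.595 of the TPM. Another 719 genes reached the minimum in replicate 2 alone and 171 in replicate 1 alone. Of the detected genes, 128 had a mean of at least 1000 TPM, 1044 lay from 100 to under 1000, 6701 from 10 to under 100 and 5498 below that. Across the 24940 genes above 0 in either library, log2(TPM + 1) correlated with a Pearson r of 0.986 and a Spearman rho of 0.967; genes are not independent replicates, so these values only describe the pair. The biological coefficient of variation was 27.7% over 18722 genes, and 13.4% in data simulated with counting noise alone and 200 changed genes. Among detected genes from 10 to under 100 TPM the median difference between replicates was 1.08-fold, and 1.64% of them differed at least 2-fold. From 1 to under 10 TPM these values were 1.13-fold and 3.86%. They were 1.08-fold and 1.34% from 100 to under 1000 TPM, and 1.13-fold and 1.56% at 1000 TPM or more.

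Trophoblast, the fetal epithelium that builds most of the placenta, was represented by large gene families. Of 25 measured members of the prolactin family, hormones of pregnancy clustered on chromosome 13, 24 were detected, and together they held 3.02% ± 0.753 of all TPM, or 1.63% of expected counts, which are not corrected for transcript length. Prl3b1 and Prl2c3 led, followed by Prl2c5 at 2357 ± 738 and Prl8a9 at 1846 ± 286 TPM, and only Prl3a1 was not detected, at 0.05 and 0.02 TPM. The family's median was 155.9 ± 9.04 TPM, at percentile 100 of the random lists in both replicates. All 21 pregnancy-specific glycoprotein and Ceacam genes were detected, with Ceacam11 at 839.7 ± 15.6, Psg21 at 504 ± 61.2 and Ceacam14 at 494 ± 22.3 TPM. Of 8 placental cathepsins, which are lysosomal proteases expanded in rodents, 5 were detected, led by Ctsj at 1855 ± 119 and Ctsr at 281 ± 52.0 TPM, and Cts6, Cts7 and Cts8 were not. Members of such families can share reads. The posterior standard deviation of Prl2c3 was 0.0235% and 0.0354% of its count in replicates 1 and 2. On mm9, however, 169755 reads lay on 1 unannotated junction between Prl2c3 and Prl2c2. The small deviation therefore does not exclude reads placed on the wrong copy.

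Markers of the placental layers differed widely in level. All 12 spongiotrophoblast and glycogen cell genes were detected, with Tpbpa and Tpbpb, the latter at 2112 ± 238 TPM, far above the homeobox gene Rhox9 at 561 ± 155 and the imprinted Phlda2 at 558.7 ± 26.3. The 10 genes of the syncytiotrophoblast and labyrinth, the exchange layer, were all detected at a median of 19.4 ± 1.18 TPM, with the connexin Gjb2 at 132 ± 26.7 and the lactate carriers Slc16a1 at 87.4 ± 2.84 and Slc16a3 at 58.1 ± 6.55. Their percentile was 98.4 in replicate 1 and 97.4 in replicate 2, so this list was above the random lists in only 1 library. Of 11 genes of the progenitor list 9 were detected, led by the keratins Krt8 at 1137 ± 51.9 and Krt18 at 988 ± 7.62 and by Hand1 at 128 ± 16.3 TPM. The stem cell factor Eomes, at 0.83 and 1.07 TPM, and Lgr5, at 1.11 and 0.84, were not. The other detected members were named after their values were seen. Id2 stood at 94.2 ± 14.2, Ets2 at 69.3 ± 2.06 and Tfap2c at 57.6 ± 9.23 TPM. Cdx2 stood at 10.1 ± 0.559, Esrrb at 2.86 ± 0.170 and Elf5 at 2.57 ± 0.849. Whether the leading genes mark progenitors alone was not tested.

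Red cell transcripts held 4.93% ± 0.248 of the TPM, or 1.78% of expected counts, and all 11 measured erythroid genes were detected (Hbb-b1 and Hbb-b2 had no entry). The embryonic globins Hbb-y at 19745 ± 757, Hba-x at 4508 ± 450 and Hbb-bh1 at 4415 ± 489 TPM summed to more than the adult ones, among which Hba-a2 stood at 11354 ± 998, Hba-a1 at 5669 ± 85.3, Hbb-bt at 2029 ± 67.8 and Hbb-bs at 1268 and 1576 in replicates 1 and 2. The ratio of embryonic to adult globin was 1.40 ± 0.031. Primitive fetal red cells make the embryonic globins and also adult alpha globins, so this ratio does not divide primitive from definitive or maternal cells. In expected counts it was 1.68. Hba-a1 and Hba-a2 are near-identical copies. The posterior standard deviation was at most 0.215% of the count for Hba-a1 and 0.135% for Hba-a2. This does not exclude reads placed on the wrong copy, since 642093 reads on mm9 lay on 1 unannotated junction between them.

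All 12 yolk sac endoderm genes were detected and held 4.47% ± 0.539 of the TPM, with the retinol carrier Rbp4 at 1532 ± 348 and Apoa4 at 1381 ± 5.40 behind Afp, Apoa1, Trf and Ttr. Whether these transcripts came from yolk sac in the samples or from the placenta itself was not tested. Of 36 imprinted genes, which are expressed from 1 parental copy, 35 were detected. After H19 came Igf2, a fetal growth factor, at 1321 ± 20.2, Meg3 at 921 ± 86.7 and Peg10, a retrotransposon-derived gene needed for placental development, at 883 ± 2.62 TPM, and Usp29 was not detected. Of 12 steroidogenic genes 10 were detected, with Hsd17b2 at 159.6 ± 13.3, Por at 88.2 ± 3.99 and Hsd11b2, which inactivates glucocorticoids, at 75.8 ± 13.0 TPM. Aromatase, Cyp19a1, had 0 and 1 counts and was not detectable at this depth, where a count of 0 allows a true level of up to 3 counts, and Hsd17b1 had 5 and 17.

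Of 21 nutrient transport genes 20 were detected, with the calcium-binding S100g at 1303 ± 89.0, the glucose carrier Slc2a1 at 281 ± 25.8, the amino acid carriers Slc38a4 at 232 ± 21.2 and Slc3a2 at 138 ± 0.346 TPM, and Calb1 was not. All 10 angiogenic factor genes were detected. Flt1, the receptor that binds vascular endothelial growth factor and placental growth factor, was highest at 146 ± 8.10, before Hif1a at 65.3 ± 1.41, Vegfa at 48.3 and 51.8 in replicates 1 and 2 and Angpt2 at 16.9 ± 0.88 TPM. Their percentiles, 94.2 and 96.9, did not reach 97.5.

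Of the lists for other cells of the uterus, the blood and the vessel wall, only the fibroblast list lay above the random lists in both replicates, at percentile 100. In the endothelial list, at percentiles 95.7 and 97.6 in replicates 1 and 2, all 11 genes were detected, with Cdh5 at 125.7 ± 2.28, Esam at 48.4 ± 4.61 and Plvap at 42.5 ± 3.71 TPM. All 10 fibroblast and matrix genes were detected, with Fn1 at 869 ± 152, Col3a1 at 535 ± 177 and Col1a1 at 341 ± 39.2. Of 12 decidual genes, markers of the transformed uterine stroma, 10 were detected (percentiles 89.8 and 96.9), with Prl8a2 at 210.5 ± 6.92 and Cebpb at 94.8 ± 6.24, whereas Des stood at 9.34 and 155.0 TPM in replicates 1 and 2. The progesterone receptor gene Pgr, at 0.10 and 1.74, and Bmp2, at 0.68 and 0.72, were not. Of 14 uterine natural killer and lymphoid genes 8 were detected (percentiles 54.7 and 65.2), led by the granzymes Gzmd at 71.5 ± 18.9, Gzmf at 65.4 ± 17.9 and Gzmg at 52.6 ± 17.3. The 6 not detected, named after their values were seen, were Ncr1, Klrb1c, Nkg7, Gzma, Cd3e and Cd19, the highest being Nkg7 at 0.17 and 0.62 TPM. Macrophage and leukocyte genes were detected in 11 of 12 cases (percentiles 84.1 and 99.9), with Csf1r at 66.6 ± 1.82 but Lyz2 at 8.14 and 118.7 TPM, and Cd163 was not. Smooth muscle genes were detected in 6 of 8 cases (percentiles 85.1 and 100), with Acta2 at 195.4 and 930.1, Actg2 at 25.9 and 590.0 and Tagln at 34.3 and 534.3 TPM in replicates 1 and 2, so that a mean says little. Of 9 uterine epithelial genes 5 were detected (percentiles 92.8 and 93.3), with Epcam at 93.3 ± 0.969, Cdh1 at 86.4 ± 0.41 and Wfdc2 at 52.4 ± 7.10, which other epithelia also express. Those not detected, named after their values were seen, were Lif at 0.76 and 1.38, Ltf at 0.38 and 0.66, Sprr2f at 0 and 0.16 and Cxcl15 at 0 TPM in both.

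Lists of general cell functions completed the profile. All 12 cell cycle genes were detected, with the mitotic kinase gene Cdk1 at 358 ± 0.806 and Pcna at 157 ± 2.72 TPM. The 10 housekeeping genes had a median of 930 ± 13.6 TPM. Immediate early and heat shock genes were detected in 8 of 10 cases, led by Dnajb1 at 69.0 ± 5.81, Jun at 23.1 ± 3.19 and Hspa1b at 21.1 ± 1.20, and Egr1 and Fosb were below the minimum in replicate 1, at 0.74 and 0.40. Mitochondrial genes held 11.5% ± 1.29 of the TPM, and 15 of 37 were detected, the 4 highest being mt-Atp8, mt-Co1, mt-Co2 and mt-Co3. The mitochondrial share was 6.10% with mt-Atp8 alone left out, a setting chosen after seeing the data, and 3.91% of expected counts. The posterior standard deviation of mt-Co3 was 18.0% and 16.5% of its count. Of 67 replication-dependent histone genes, whose transcripts lack polyA tails, 56 were detected, with Hist1h2af at 269 ± 107 and Hist1h2bc at 261 ± 0.849 TPM, but the list held only 0.165% ± 0.0209 of the TPM and 0.0521% of expected counts. In the background list of 16 genes from other organs, 3 were detected, the fetal liver and yolk sac product Alb at 294 ± 40.5, the muscle gene Acta1 at 2.68 and 27.5 in replicates 1 and 2, and Cela1 at 4.95 ± 1.87, and the median was 0.0675 ± 0.053 TPM. In all, 14 of the 26 lists lay above the random lists in both replicates. The steroidogenic and histone lists were among them but fell to percentiles 93.8 and 26.6 against random lists of detected genes.

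The genes highest in replicate 2 included several of fat and smooth muscle. Cfd, the adipose serine protease adipsin (chromosome 10, 79890853 to 79892655), stood at 0.89 TPM in replicate 1 and 589.65 in replicate 2, a 640.0-fold difference in scaled counts with a 95% counting interval from 517 to 801. Adipoq, the fat cell hormone adiponectin (chromosome 16, 23146536 to 23158028), had 10 and 9685 counts, a 1003-fold difference with an interval from 545 to 2092. Myh11, the myosin of smooth muscle (chromosome 16, 14194535 to 14291372), was 83.9-fold higher in replicate 2 (interval 78.9 to 89.3), and Cnn1, smooth muscle calponin, 124-fold (109 to 141). Car3, Cyp2e1, Mgp, Pdlim3, Dpt and Tnxb completed the 10 genes highest in replicate 2, at ratios from 59.2 for Mgp to 569 for Car3. These folds of single genes are ratios of scaled counts with nothing added. For the counts of genes, 1 was added to each scaled CPM, which shrinks the ratios of genes with few counts. On that scale, of 15107 genes compared, 524 were at least 2-fold higher in replicate 2 and 18 in replicate 1, and 66 were at least 8-fold higher in replicate 2 against 0 in replicate 1. The 2-fold counts were 658 and 9 under spike-in scaling, and 718 and 40 with 0.1 instead of 1 added to the CPM.

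Genes higher in replicate 1 differed by less. Serpina6, which encodes the corticosteroid carrier of the blood, had 505 and 48 counts, a 10.2-fold difference (interval 7.55 to 14.0). The chromatin protein gene Hmga2 was 3.60-fold higher in replicate 1 (3.36 to 3.86), Zfhx4 3.59-fold, Sox11 2.98-fold, Prap1 2.90-fold and the proliferin Prl2c2 2.47-fold. The other 4 of the 10 highest in replicate 1 were the processed pseudogenes Gm4540 and Gm10132 and 2 gene models without a symbol. This is 1 library against 1 of the same tissue, so the ratios carry no replicate check and no p-value. When every gene was simulated with a coefficient of variation of 30%, 1111 of 14871 unchanged genes passed the 2-fold rule. In the real pair only 542 of 15107 genes (3.59%) passed it, so by the 2-fold rule the simulated spread was wider than the real one. The simulation gave every gene the same spread, whereas 66 real genes were at least 8-fold higher in replicate 2 and 0 in replicate 1. The simulation therefore cannot decide whether a single gene near 2-fold lies within the spread between these libraries.

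**Figure D2:**
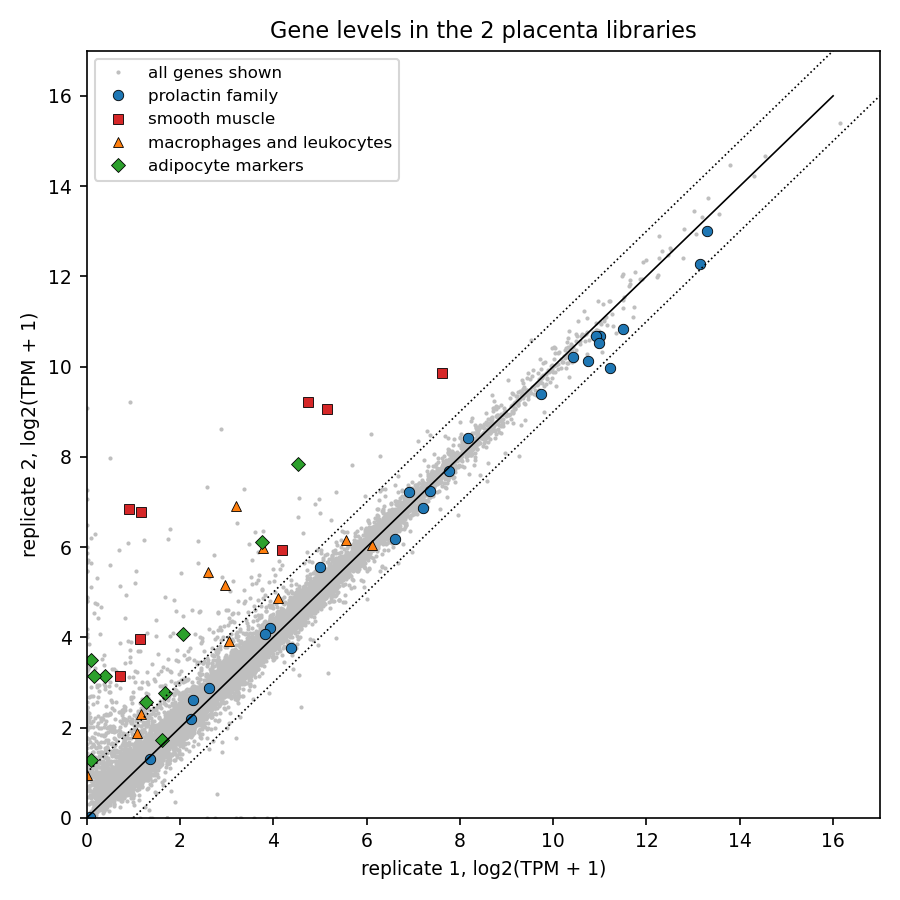
Each point is a gene, with log2(TPM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis; the solid line marks equality, dotted lines a 2-fold difference, and coloured symbols the members of 4 gene lists. Smooth muscle genes lie above the upper dotted line, whereas prolactin genes lie near the diagonal or below it.

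As lists, 9 of the 25 compared lay above their matched random lists in the ratio of replicate 2 to replicate 1, and 10 lay below. The smooth muscle list had a median log2 ratio of 3.71, a 13.1-fold difference, and 8 of 8 members were at least 2-fold higher in replicate 2. Macrophage and leukocyte genes followed with a median ratio of 2.83-fold, with 7 of 12 at least 2-fold higher, among them Lyz2 and the complement gene C1qb. Uterine natural killer and lymphoid genes had a median of 0.59, fibroblast and matrix genes 0.33, decidual genes 0.26, mitochondrial genes 0.29, immediate early genes 0.28 and yolk sac genes 0.17. The decidual count of 3 genes past 2-fold included Des, which smooth muscle also expresses.

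Trophoblast lists lay on the other side by small amounts. The medians were -0.33 for the syncytiotrophoblast and labyrinth, -0.29 for the prolactin family, -0.23 for cathepsins, -0.21 for spongiotrophoblast, -0.20 for pregnancy-specific glycoproteins and -0.16 for progenitors, with 1 prolactin gene and no other member of these lists past 2-fold. Erythroid genes at -0.21, imprinted genes at -0.15, steroidogenic genes at -0.14 and histones at -0.12 were also below their random lists, but with a count minimum of 10 the steroidogenic median was -0.02 and within them. The endothelial median of -0.13, the uterine epithelial one of 0.04, angiogenic factors at -0.06, housekeeping at -0.07, cell cycle at -0.10 and nutrient transporters at 0.03 were within the range of random lists. Scaling on spike-ins raised the median ratio of all genes by 0.23 and turned 12 of these medians positive, including all of those given here as negative except the prolactin and labyrinth ones, while each of the 9 and 10 lists outside its random lists stayed on the same side of them.

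**Figure D3:**
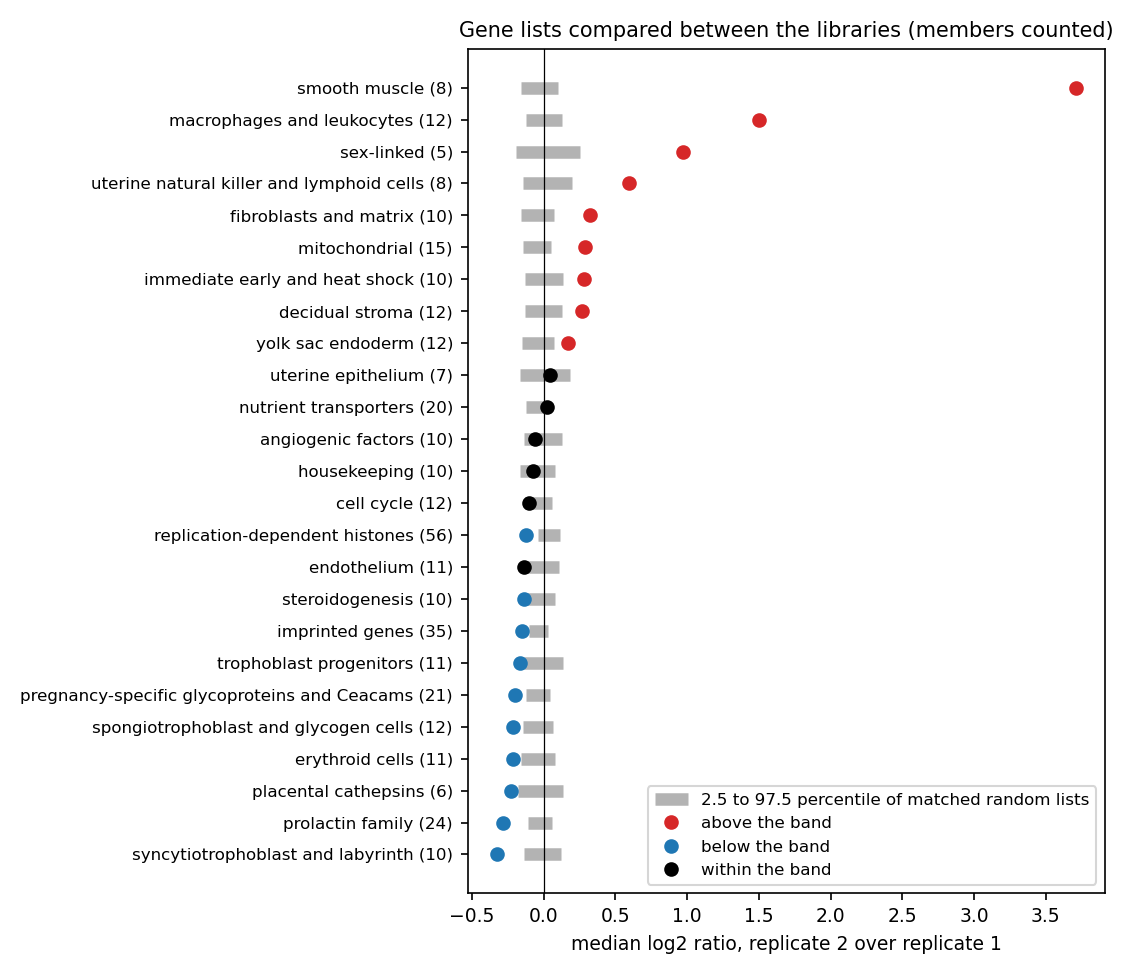
Median log2 ratio of replicate 2 over replicate 1 (x axis) for the 25 lists with at least 5 members counted; grey bars span the 2.5 to 97.5 percentile of 10000 matched random lists, and the number of members stands in brackets. Smooth muscle lies far to the right at 3.71, macrophages follow, and the trophoblast lists lie slightly left of their bars under TMM scaling (spike-in scaling moves most medians above 0).

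Sex-linked genes differed as well. Xist, the RNA that silences an X chromosome in female cells, stood at 100.7 TPM in replicate 1 and 49.4 in replicate 2. All 4 Y-linked genes were higher in replicate 2, with Ddx3y at 3.24 and 11.3, Eif2s3y at 6.02 and 12.3, Uty at 1.30 and 4.66 and Kdm5d at 1.78 and 3.90 TPM. In scaled counts the ratios of replicate 2 to replicate 1 were 0.486 for Xist, 3.33 for Ddx3y and Uty, 2.10 for Kdm5d and 1.89 for Eif2s3y. Both libraries held transcripts of Xist and of the Y chromosome.

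The transcripts of Flt1 were unequally used. Flt1-203, which has 13 exons and encodes 688 codons (chromosome 5, 147635159 to 147725988, minus strand), held 56.6% ± 3.74 of the gene's TPM, whereas Flt1-202, the full-length receptor with 30 exons and 1333 codons, held 16.2% ± 2.09. The short form ends before the exons that encode the membrane-spanning part and the kinase, and is the known soluble receptor of the placenta. A noncoding transcript of 12 exons, Flt1-201, held 26.6% ± 5.73. In expected counts, which are not corrected for length, Flt1-201 held 7731 and 10455 in replicates 1 and 2. Flt1-202 held 21977 and 18120, so the order of Flt1-201 and Flt1-202 depends on length scaling. The difference between the coding forms was far larger than the spread between replicates.

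**Figure D4:**
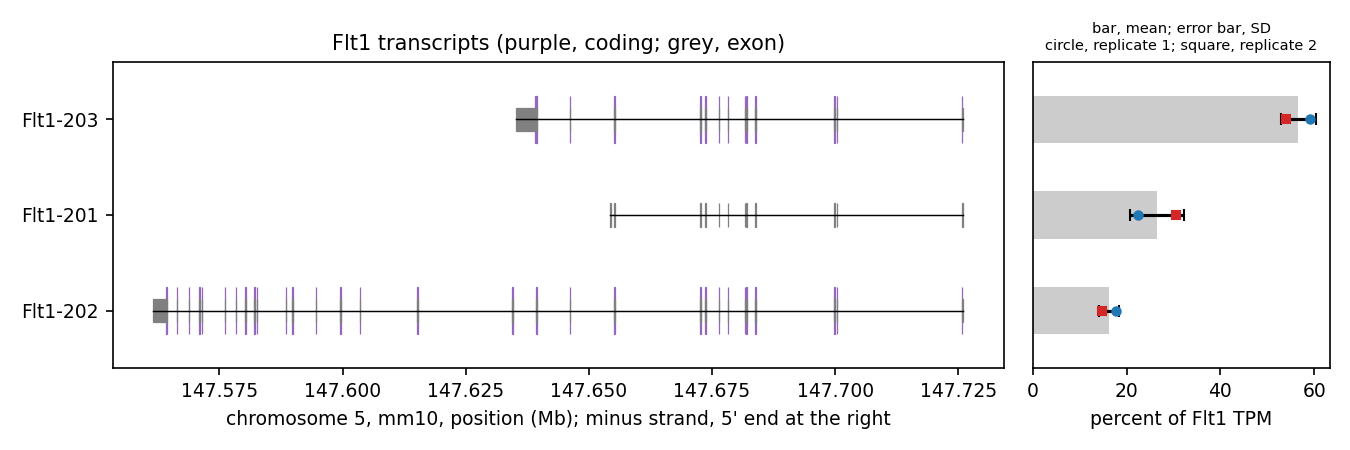
Left, exons of the 3 Flt1 transcripts with the highest shares along chromosome 5 (mm10, position in Mb); right, percent of Flt1 TPM (bar, mean; error bar, SD of 2 replicates; circle, replicate 1; square, replicate 2). Flt1-203 ends upstream of most exons of Flt1-202 and holds 56.6% ± 3.74.

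For Igf2, the noncoding transcript Igf2-208 held 53.5% ± 2.40 and the coding Igf2-201 32.4% ± 4.72. Igf2-208 has 958 bases and lies within the span of Igf2-201, which has 3708 bases. In expected counts, which are not corrected for length, Igf2-208 held 68145 and 68835 in replicates 1 and 2. Igf2-201 held 216672 and 164999, so the lead of Igf2-208 holds only after length scaling. Leading transcripts of other genes were Slc2a1-201 at 99.3% ± 0.0283, Ascl2-201 at 80.8% ± 6.91, Gnas-208 at 77.3% ± 0.262, Grb10-201 at 76.3% ± 4.15, Cdkn1c-201 at 67.4% ± 3.14, Mest-211 at 65.04% ± 5.99 and Peg10-203 at 60.4% ± 0.856. Tfrc-201, the transferrin receptor, held 52.4% ± 0.87, with 41.8% ± 0.509 on a transcript with a retained intron. Vegfa was spread over 11 annotated transcripts with none above 26.5% ± 0.198, and Pgf had only 1.

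The spike-in RNAs took 3.41% of the counts in replicate 1 (interval 3.40 to 3.41) and 2.85% in replicate 2 (2.84 to 2.85), or 3.13% ± 0.396. These intervals did not overlap, although they cover counting error only. The authors' pooled values on the older build ranked genes much as the newer TPM did, with a Spearman rho of 0.937 and a Pearson r of 0.934 on log2 values across the 21613 genes above 0 in both.

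On mm9, the deposited junction file listed 1451175 splice junctions with 192350081 reads. Junctions marked as annotated were 13.0% of all junctions and held 95.7% of the reads, and all 188909 of them joined exon edges of the Ensembl V65 exons. Of the 1262266 unannotated junctions, 873954 rested on 1 read. Among the 208888 junctions with at least 10 reads, 75.4% were annotated. The contig file listed 748599 transcribed segments that covered 660.3 Mb of strand-specific sequence. Those touching an exon on the same strand were 16.1% of contigs and 45.6% of their length, intronic ones 39.4%, antisense ones 12.2% and intergenic ones 32.3% of contigs.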

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

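The test of exon order below was chosen after the result was seen, and the other tests before it. Reads assigned to phiX, a viral control DNA added to sequencing runs, numbered 757316 in replicate 1 and 675651 in replicate 2, or 0.464% and 0.427% of the counts, well above the limit of 3 counts that a count of 0 allows. Of 135900 transcript models assembled on mm9, 44301 lay outside every Ensembl V65 gene on either strand and held 19.8% of the summed score. The highest scores among them, 1000 and 768, belonged to adjoining models on chromosome 1 (24621723 to 24623088, mm9, minus strand). The pseudogenes that share reads with mitochondrial genes lie at similar positions on mm10. Whether these models hold mitochondrial reads was not tested, so the share is no measure of unannotated genes. The assembled models enter no comparison above, and the phiX reads enter only as part of the total counts and of the TPM sum.

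Another signal outside the main measurements was 5439 unannotated junctions with canonical splice sites that joined exon edges of 2 different genes, with 2353712 reads or 28.6% of the reads on unannotated junctions. The strongest, 1 for each pair of genes and named after their values were seen, ran from Hba-a1 to Hba-a2 (chromosome 11, 32184129 to 32197079, mm9, 642093 reads), between Prl2c2 and Prl2c3 (169755), between Hbb-bs and Hbb-bt (135868), between Tuba1b and Tuba1a (51001) and between Tpbpa and Tpbpb (37486). Of the reads between genes with a transcript sequence, 98.9% lay between genes that share at least 1 word of 31 bases. The other 1.11% lay between genes that share none, which argues against read-through of unrelated neighbours as the main source of the reads. By junction the shares were 73.0% and 27.0%. Between the copies, 96.1% of the reads joined exon n of 1 gene to exon n + 1 of the other. For the reads, this argues against read-through from the end of 1 copy into the next. By junction the share between copies was only 70.1%, which leaves the remaining junctions undecided. Between genes that share no word it was 87.5% of the reads, so exon order hardly sets the copies apart from this class. Its strongest pairs, named after their values were seen, were Prl8a9 with Prl8a1 (4530 reads) and Ctsj with Ctsq (2536). These are members of the same families, so the class does not show how unrelated genes would behave. Alignment of a read pair or its parts to the wrong copy may account for most of these reads, and no biological explanation besides read-through was tested.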

How the results depend on the processing

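Leaving out mt-Atp8 or genes of uncertain count was chosen after seeing the data. Over 106 results and 509 values under an alternative, 421 were the same, 71 moved, 3 lost and 14 gained a place outside the random lists, and 0 reversed. Same means the same call for a list, a change below 1 SD of the replicates for a share or ratio, within 1.5 times for a count of genes, junctions or lists, and equality to 2 decimals for a correlation or coefficient of variation (as a fraction). For a list or isoform share, the globin ratio or the spike-in share, each replicate alone lies within 1 SD of the mean by arithmetic. Those values count as the same by construction and say nothing of stability. The smooth muscle share, for example, was 0.0277% in replicate 1 and 0.236% in replicate 2. The cause was not tested unless stated. The number of detected genes stayed within 1.5 times under all 6 alternatives. A pseudocount of 0.1 gave a Pearson r of 0.980, and no filter on low counts a coefficient of variation of 32.5%. With mitochondrial genes and spike-ins out of the denominator, the 10 and 25 most abundant genes held 14.4% and 22.0%, erythroid genes 5.88% and yolk sac genes 5.32%. As percent of expected counts, which are not corrected for length, the 10 and 25 genes with the most counts held 12.1% and 17.01%. On the same scale erythroid genes held 1.78%, yolk sac genes 5.86% and the prolactin family 1.63%, and the globin ratio was 1.68. With mt-Atp8 alone left out, erythroid genes held 5.24% and mitochondrial genes 6.10%. Genes higher in replicate 2 numbered 916 at 1.5-fold and 182 at 4-fold. Those higher in replicate 1 numbered 106 at 1.5-fold, 0 at 4-fold (with 1 added to the CPM), 40 with 0.1 added and 9 under spike-in scaling. This small count thus depends on the setting. Leaving out genes of uncertain count took the counts to 515 and 13. The smooth muscle and decidual lists stayed above their random lists under each other scaling, count minimum and prior. The endothelial list passed below its random lists under spike-in scaling, with a median of 0.11, and the steroidogenic list lost its place with a count minimum of 10, at -0.02. In levels, each replicate alone put smooth muscle at percentile 85.1 or 100 and macrophages at 84.1 or 99.9, so replicate 1 keeps both below the 97.5 set for both replicates. Posterior mean TPM put the labyrinth, decidual, macrophage, endothelial, uterine epithelial, angiogenic and immediate early lists above their random lists. In that setting the random lists were drawn from genes with a posterior mean above 0. The reference thus changed along with the list values, and the 2 effects were not separated. Random lists of detected genes took the steroidogenic (93.8) and histone (26.6) lists out. Junctions fell to 208888 with at least 10 reads and to 238456 at an irreproducibility rate of at most 0.1, and contigs to 368695, by the construction of stricter thresholds. Depth limits what can be said of Cyp19a1, at 0 and 1 counts, and with n = 2 no spread can be estimated for a single gene with any precision.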

Other observations

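The tests of trophoblast share, male share and maternal share, the added lists of adipocyte and smooth muscle genes, and the gene families outside the fixed lists, picked from a look over gene-name patterns and the most abundant genes, were chosen after the values were seen. Several families outside the fixed lists were abundant in both libraries. The Serpinb9 family, protease inhibitors clustered on chromosome 13, had 7 members that summed to 914 ± 152 TPM, led by Serpinb9e at 355 ± 47.6 and Serpinb9g at 182 ± 34.9. Sct, the hormone secretin, stood at 1801 ± 138 TPM, the metallothioneins Mt1 and Mt2 at 1965 ± 43.7 and 1741 ± 129, and the keratins Krt19 and Krt7 at 498 ± 92.5 and 253 ± 6.48. In the X-linked Rhox cluster, Rhox5 was nearly equal in both libraries at 743 ± 1.34 TPM, whereas Rhox12 was lower in replicate 2, at 26.6 against 44.4. RNA polymerase III transcripts were present in spite of the polyA selection, with Rn7sk at 2779 ± 826 and Rmrp at 437 ± 253 TPM.

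Genes of antigen presentation and antibodies were among those far higher in replicate 2. The 4 class II genes stood at 2.47 and 83.1 TPM for Cd74, 1.09 and 43.1 for H2-Aa, 3.04 and 41.8 for H2-Ab1 and 0.80 and 29.7 for H2-Eb1 in replicates 1 and 2, ratios of 13.2 to 38.4 in scaled counts. The immunoglobulin genes Igkc and Ighm stood at 2.35 and 71.4 and at 2.21 and 28.8 TPM. Class I genes differed less, with H2-K1 at 101.2 and 189 and H2-D1 at 97.0 and 164.9. Of the insulin-like growth factor binding proteins, Igfbp6 was 75.4-fold and Igfbp7 4.30-fold higher in replicate 2, while Igfbp4 at 176 ± 26.3 TPM and Igfbp2 at 43.6 ± 2.39 were close in both.

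Smooth muscle and fat genes were higher in replicate 2, as given above for Myh11, Cnn1, Cfd and Adipoq. A difference in scaling is argued against, because the smooth muscle median was at least 3.70 on the log2 scale under all 4 scalings. A smaller share of trophoblast RNA is argued against as the whole cause, because it would raise every other cell type alike, and the smooth muscle median lay 3.84 above the endothelial one. Added lists of 10 adipocyte markers and 12 further smooth muscle genes, of which replicate 1 also expressed 6 and 8, had medians of 2.39 and 2.25 over the 10 and 11 past the count minimum (Chrm2, below it, was lower in replicate 2, at 0.06 against 0.14 TPM), with Fabp4 at 22.3 and 229.6 and Myl9 at 67.2 and 362 TPM in replicates 1 and 2. A candidate explanation is that uterine wall and adjoining fat were taken along with replicate 2, and a difference in stage or in the animals stays open as untested.

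Xist was lower and the Y-linked genes were higher in replicate 2. Reads shared with the X homologues (median level of the 4 homologues 65.2 ± 8.63 TPM) are argued against, since the posterior standard deviation of the Y-linked counts was 0% of their difference. A larger share of maternal tissue in replicate 2 is argued against as the whole cause, since female tissue would lower Y-linked genes and their median log2 ratio was 1.25. A larger male share of the tissue may account for both directions, for example if the samples pooled conceptuses of both sexes in different numbers, but a first test of it was discarded because any lower Xist with higher Y-linked genes meets it. The Y-linked ratios differed among themselves by up to 1.77 times, more than the 1.5 times set for a single change in share, so this explanation stays open, and the labels say that sex was not collected.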
